A study of Gallus gallus with 4 samples.

How the data were processed

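H3K27ac, the acetylation of lysine 27 of histone H3 found at active promoters and enhancers, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in chicken neural crest cells, the migratory cells that build much of the face. There were 4 libraries, an H3K27ac ChIP and an input (sonicated DNA without immunoprecipitation) at each of 2 stages, and 1 library in each group. Per the labels, the early cells came from dorsal neural tube explants taken at Hamburger-Hamilton stage 8 and cultured for 48 to 72 h, and the submitters took the cranial cells that had migrated out to resemble stages 11 to 14. The late cells were dissected from the frontonasal prominence, the tissue of the upper midface, at stage 20, after surface ectoderm and forebrain neuroectoderm had been removed. Cells were pooled at each stage. Per the labels' protocols, libraries were size selected at 200 to 700 bp, amplified by 18 cycles of PCR and sequenced on an Illumina Genome Analyzer, and the antibody was Abcam's against acetylated lysine 27.

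The authors deposited the position and strand of each aligned read as a short mark, which the file headers name as made by QuEST, and 1 list of called regions per ChIP library. The header of the early ChIP library calls it stage 8, the stage at which the explants were taken. Both ChIP headers carry the word cutoff3, whose meaning is not given in the sources used here. The deposited region lists hold a start, an end, a rank and a score. What the score measures is not named in the files, so it was used only to rank regions within its own list. Ranks run to 27294 for the 27293 regions of st11-14 and to 12664 for the 12660 of st20, so 1 and 4 ranks have no region. The lowest score was 4.00 at st11-14 and 4.03 at st20. The aligner, the genome build, the read length, the filter on duplicate reads and the control used for calling are not given in the sources used here. The ChIP libraries held 377924 start positions with exactly 2 reads at st11-14 and 472 with exactly 3. At st20 these numbers were 1110626 and 3629. Of the positions with 2 reads, 75.8% lay in st11-14 regions at st11-14 and 43.3% in st20 regions at st20.

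Reads were counted at the 5 prime end moved 100 bp inward, with 1 read kept per position and strand. The offset between reads of the 2 strands, a measure of fragment length, was estimated at 284 bp in the st11-14 ChIP and 116 bp in the st20 ChIP. The same shift was used for both. The deposited files held 8623288 reads for the st11-14 ChIP, 7569335 for its input, 25752187 for the st20 ChIP and 32428962 for its input. Distinct starts numbered 8234124, 7539274, 24581803 and 31895477 in that order. The st20 ChIP library was 2.99 times as deep as the st11-14 ChIP library, so its counts carry less counting error. The reads carry no molecular identifiers, and all intervals and limits cover counting error only.

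Shares of reads in called regions are given with 95% Wilson intervals. Densities are distinct starts per kb and per 1000000 distinct starts of the library, and the chromosome background is the density outside all called regions. Overlap of the lists counted 1 bp or more, and the chance level came from 1000 random rotations of the other list within each chromosome. For the comparison of stages, the lists were merged into 29354 union regions and st20 counts were scaled to the st11-14 depth. The log2 ratio of st11-14 to st20 was taken with a pseudocount of 1 read and centred on the 9107 regions called at both stages, whose median before centring was 0.27. With 1 library per group there is no replicate error, so no test was run and no p-value is given. A region was called higher at a stage by a rule of size: a ratio of at least 4, at least 20 scaled reads at that stage, ChIP over input of at least 2 there, and an exact (Clopper-Pearson) 95% interval of the ratio that excluded 1. All exact intervals of the ratio between stages were taken on counts without the pseudocount, so they are not centred on the printed log2 ratios. ChIP over input was taken on depth-scaled counts with a pseudocount of 1. On simulated counts for 29354 regions of this comparison, the rule recovered 47% of 100 regions changed 4-fold and 100% of 100 regions changed 8-fold, and called 0 unchanged regions. Under a minimum of 2-fold the same step called 50 unchanged regions. The simulation held counting error only, and its changed regions had at least 20 expected reads at the st11-14 depth before the change. Its input was capped well below the ChIP reads, so it did not test the minimum of ChIP over input. Without that minimum, 1770 regions of the data were higher at st11-14 and 698 at st20.

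These choices, the alternatives and the rule for named regions were fixed before the data were examined. The named regions are the 10 with the highest and the 10 with the lowest log2 ratio among those that pass the rule, and the 5 union regions per stage with the most ChIP reads after subtraction of depth-scaled input. Runs of neighbouring regions were defined after the values were seen, as regions passing the rule in the same direction with gaps of at most 50 kb. Their chance level came from 100 shuffles of the rule's calls among union regions of the same chromosome that were called at the same stage or stages. Regions were also stitched into domains over gaps of up to 12.5 kb. Alternatives covered duplicate reads, the read shift, scaling, input subtraction, pseudocount, the minimum fold and reads, depth, 1 kb windows, and the overlap and score required. Others, chosen after the data were seen, covered the control at each stage, input starts shared with the ChIP, the minimum of ChIP over input, the fragment length and regions with high input.

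Positions are 1-based and are those of the deposited files. Their genome build is not given in the sources used here, no genome sequence was used, and the gene table at hand is tied to the GRCg7b assembly, so no gene, promoter or motif was assigned to a region. The planned promoter shares, motif shares and tests of 15 gene lists, and the genes NR2F1 and NR2F2 named in the study's title, were therefore not analysed here. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.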

Results

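H3K27ac was mapped in chicken neural crest cells that had migrated from cultured stage 8 dorsal neural tube (st11-14) and in neural crest cells of the stage 20 frontonasal prominence (st20). Each stage had 1 ChIP and 1 input library, so the comparisons describe these libraries and have no replicate check. The early cells were cultured and the late cells dissected. Every difference between stages below therefore cannot be told apart from one of tissue source, culture or library preparation. The deposited lists held 27293 regions at st11-14, with a median width of 1338 bp and 44.9 Mb in all. The st20 list held 12660 regions, with a median width of 1735 bp and 28.8 Mb in all. Regions wider than 5 kb made up 2.30% of the st11-14 list (627 regions) and 7.19% of the st20 list (910 regions).

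The first comparison asked how far acetylated chromatin stood above input at each stage. Regions called at st11-14 held 25.34% of the st11-14 ChIP reads (95% Wilson interval 25.31 to 25.37%) and 4.73% of the st11-14 input reads (4.71 to 4.74%), a 5.36-fold difference. Regions called at st20 held 13.89% of the st20 ChIP reads (13.88 to 13.90%) and 5.29% of the st20 input reads (5.28 to 5.30%), a 2.63-fold difference. Each list was called from the ChIP library counted here, so some excess over input is built in. In the libraries of the other stage, st11-14 regions held 13.92% of the st20 ChIP and 6.86% of the st20 input reads. The st20 regions held 13.91% of the st11-14 ChIP and 2.71% of the st11-14 input reads. At the midpoints of st11-14 regions, the st11-14 ChIP density was 3.73 times that 3 kb away, and the st20 ChIP density 2.27 times. At the midpoints of st20 regions, the st20 ChIP density was 3.12 times that 3 kb away, and the st11-14 ChIP density 3.74 times. The region with the most input-subtracted reads was the same at both stages, a 31295 bp stretch of chromosome 15 (407376 to 438670). It held 2841 ChIP and 303 input reads at st11-14, and 6797 ChIP and 2819 input reads at st20, with a log2 ratio between stages of 0.05 (95% exact interval -0.02 to 0.11). A 43256 bp region of chromosome 14 (4209131 to 4252386) was also among the 5 highest of both stages, with a log2 ratio of 0.25 (0.18 to 0.31).

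The other highest regions at st11-14 lay on chromosome 10 (20029600 to 20053145), chromosome 5 (30735476 to 30764104) and chromosome 20 (9973128 to 9990983). Their log2 ratios lay between 0.19 and 0.37, and all were called at both stages. The other highest regions at st20 leaned the opposite way, which picking each set by the reads of its own stage favours. Ranking by reads per region also favours wide regions, as the median width of union regions was 1505 bp. A 29191 bp region of chromosome 20 (13807253 to 13836443) had 2.52 times as many scaled ChIP reads at st20 (log2 ratio -1.34, interval -1.44 to -1.23), and a 21017 bp region of chromosome 17 (5658126 to 5679142) had 2.67 times (-1.42, interval -1.53 to -1.30). An 18863 bp region of chromosome 24 (993119 to 1011981) held 236 ChIP reads at st11-14 and 3635 at st20. Its ratio was 6.21-fold in favour of st20 (log2 ratio -2.64, interval -2.84 to -2.45), and among these high regions it alone passed the rule of size.

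The st20 input was not flat over these regions. It stood 1.56 times higher at the midpoints of st20 regions than 3 kb away, where the st11-14 input was at 0.80 of its level 3 kb away. The st11-14 input had 2.71% of its reads in the st20 regions, and with that input as control the st20 difference was 5.13-fold in place of 2.63-fold. With the st20 input as control, the st11-14 difference was 3.69-fold in place of 5.36-fold.

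The st20 ChIP and the st20 input had 2049621 read starts at the same position and strand, 3.56 times as many as at positions 1 bp apart. The st11-14 ChIP and input had 41401, or 1.04 times as many.

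**Figure D1:**
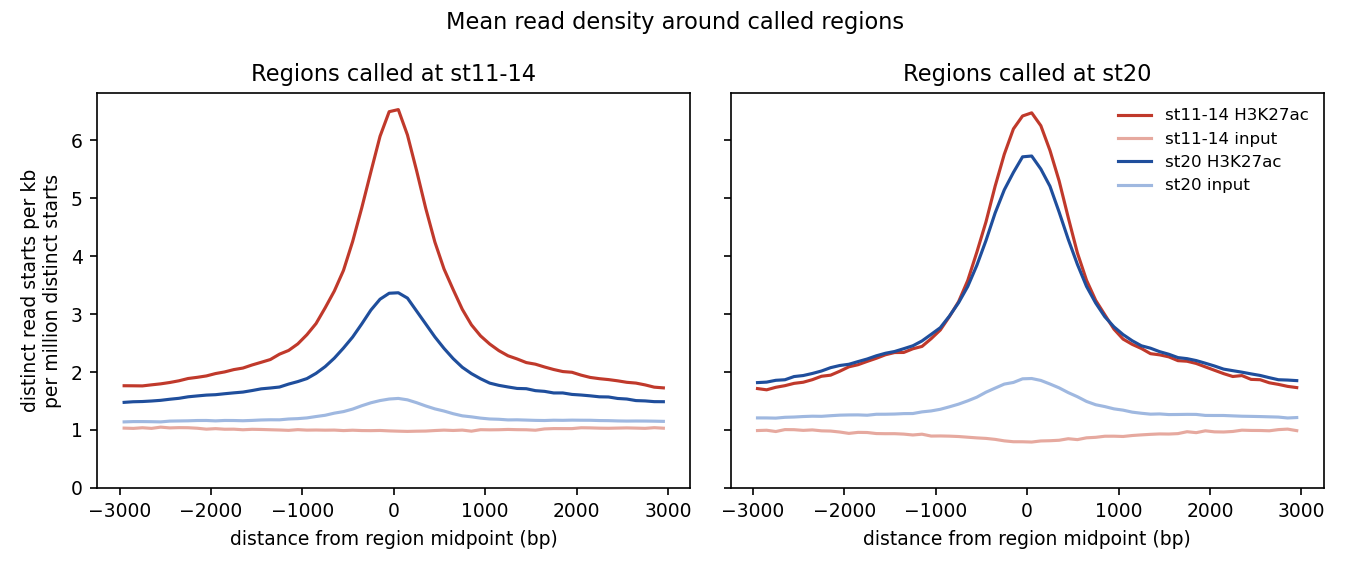
Mean density of distinct read starts (per kb and per 1000000 starts of the library, vertical axis) in 100 bp bins within 3 kb of the midpoints of the regions called at st11-14 (left) and st20 (right), 1 line per library. The ChIP libraries peak at the midpoints in both panels, the st20 input rises to 1.89 in st20 regions and the st11-14 input dips to 0.79 there.

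**Figure D2:**
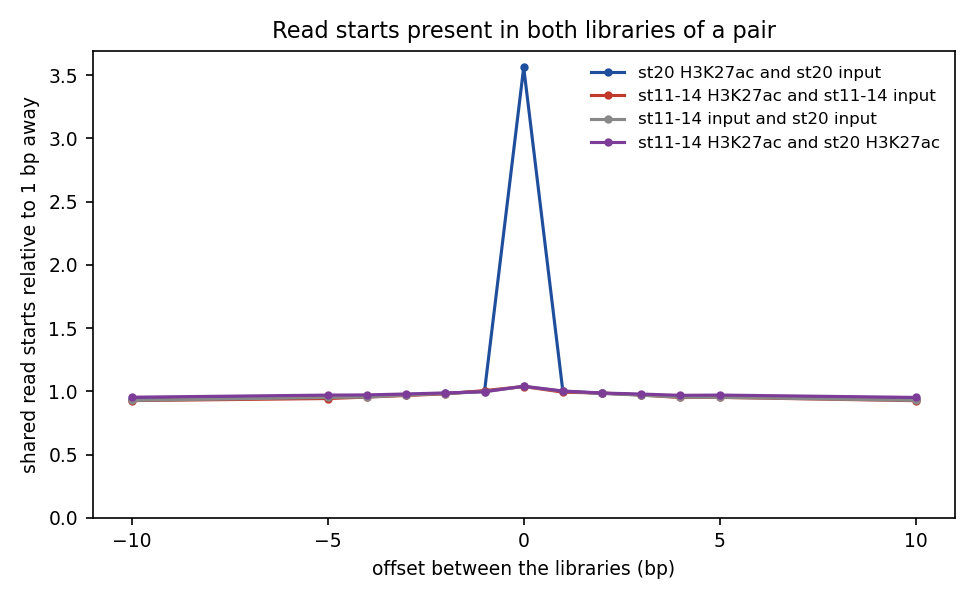
Read starts present in both libraries of a pair (vertical axis, relative to the mean of offsets of 1 bp) against the offset in bp between the libraries (horizontal axis), for 4 of the 6 pairs. The st20 ChIP and input reach 3.56 at offset 0 and the other pairs drawn lie at 1.04.

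The second comparison asked how much of the acetylated landscape the stages shared. Of the st11-14 regions, 10170 (37.3%, 95% Wilson interval 36.7 to 37.8%) overlapped a st20 region, against a mean of 5.37% and a highest value of 6.84% over 1000 rotations of the st20 list. Of the st20 regions, 9535 (75.3%, 74.6 to 76.1%) overlapped a st11-14 region, against a mean of 10.8% and a highest value of 13.3% after rotation. Shared regions were wider in the median. The median width of st11-14 regions was 1564 bp with a st20 overlap and 1196 bp without. In the top 10% of each list by the authors' score, 87.0% of st11-14 and 96.0% of st20 regions overlapped the other list, and in the lowest 10% 14.3% and 50.8%. With the 6330 highest-scoring regions of each list, the share was 60.0% for st11-14 regions and 60.2% for st20 regions.

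The third comparison asked which regions differed in H3K27ac between the stages, where stage goes together with cultured or dissected source. Of 29354 union regions, 1747 were higher at st11-14 by the rule of size and 534 were higher at st20. The counts do not measure a balance between stages, because more union regions were called only at st11-14. Regions called at both stages stood at a median of 6.69 times the chromosome background in the st11-14 ChIP and 4.96 times in the st20 ChIP. The weaker rise at st20 may leave less room for a 4-fold ratio towards it, which centring on a median does not remove. Among the 9107 regions called at both stages, 8234 (90.4%) lay within 2-fold of each other after centring, 4 were higher at st11-14 and 19 were higher at st20. Regions called only at st11-14 numbered 17122 and had a median log2 ratio of 1.19, and 1743 of them passed the rule. Regions called only at st20 numbered 3125, had a median of -1.48, and 515 passed. The lists were called from the ChIP libraries compared here, so the direction in these classes is largely built in. The log2 ratio was positive in 97.3% of regions called only at st11-14 and in 0.032% of those called only at st20. Calling at both stages and centring on that set likewise favour the 90.4% within 2-fold. Scaling to total reads, without centring, gave 3281 regions higher at st11-14 and 339 higher at st20, so that the st11-14 share of all such regions moved from 76.6% to 90.6%. The counts were 7856 and 1315 with input subtracted and 9228 and 2102 with a minimum of 2-fold, while a pseudocount of 5 left 738 regions higher at st11-14 and all deposited reads gave 816 higher at st20.

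**Figure D3:**
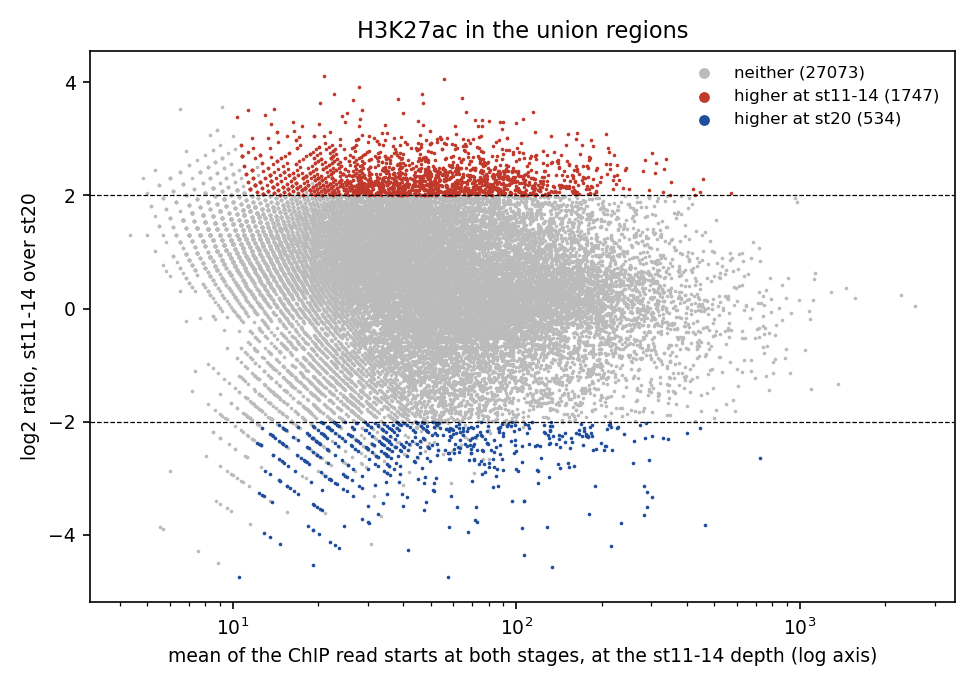
Log2 ratio of H3K27ac reads at st11-14 over st20 (vertical axis) against the mean read starts of both stages at the st11-14 depth (horizontal log axis), 1 point per union region. Red points mark the 1747 regions higher at st11-14 and blue points the 534 higher at st20, and dashed lines mark a ratio of 4 in each direction.

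The regions higher at st11-14 had a median of 7.001 times the chromosome background in the st11-14 ChIP and 0.95 times in the st20 ChIP. The highest ratio was at chromosome 9, 17991671 to 17992419, with 41 st11-14 and 3 st20 ChIP reads and a log2 ratio of 4.12 (95% exact interval 3.43 to 7.41), or 2.68 with a pseudocount of 5. A second region of the same stretch, 17982395 to 17983118, held 39 and 5 reads (log2 ratio 3.63, interval 2.92 to 5.97). The best covered of the 10 highest was on chromosome 1, 18061708 to 18063319, with 122 and 20 reads (3.72, interval 3.22 to 4.67), followed by chromosome 4, 10592304 to 10593652, with 107 and 13 reads (4.06, interval 3.51 to 5.30). The remaining 6 lay on chromosome 7 (30108984 to 30110194), chromosome Z (42528679 to 42529467), chromosome 5 (34618629 to 34620141), chromosome 1 (105528766 to 105530470), chromosome 2 (95363606 to 95364852) and chromosome 4 (9137161 to 9139250). Their log2 ratios ran from 3.63 to 3.92. All 10 had been called only at st11-14, and with a pseudocount of 5 their log2 ratios ran from 2.46 to 3.32.

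Some regions passing the rule lay in runs, which, with their chance level, were defined after the values were seen. Of the 1747 regions higher at st11-14, 670 (38.4%) had a neighbour of the same class within 50 kb, against a mean of 27.2% and a highest value of 30.2% over 100 shuffles. The run with the most regions held 12 such regions among 13 union regions over 64.4 kb of chromosome 9 (17927973 to 17992419), with 679 st11-14 and 237 st20 ChIP reads in the 12 regions and 65 and 536 input reads. Runs of 10 regions lay on chromosome 1 (148498035 to 148652206) and chromosome 4 (4484283 to 4567259). The shuffles were matched on chromosome and calling stage but not on width or reads, which bear on passing the rule. Regions higher at st11-14 had a median width of 1703 bp, against 1196 bp for those called only at st11-14. The excess over shuffles therefore cannot be told apart from clustering of wide or well covered regions.

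The regions higher at st20 had a median of 4.99 times the background in the st20 ChIP, 1.19 times in the st11-14 ChIP and 1.87 times in the st20 input. The lowest ratio was at chromosome 6, 16153609 to 16154759, with 4 st11-14 and 330 st20 ChIP reads and a log2 ratio of -4.75 (95% exact interval -6.95 to -3.69). A 533 bp region of chromosome 3 (1882854 to 1883386) had 0 ChIP reads at st11-14 and 63 at st20, and the exact interval of its log2 ratio lay below -2.75. It also had 0 input reads at st11-14 and 16 at st20, so absent acetylation cannot be told from absent coverage there. Neighbouring regions of chromosome 5 at 23838798 to 23841087 and 23842600 to 23845518 held 11 and 602 reads (log2 ratio -4.35, interval -5.48 to -3.62) and 12 and 764 reads (-4.58, interval -5.65 to -3.87). The widest of the 10, 5217 bp of chromosome 2 (68198522 to 68203738), held 26 and 1216 reads, a log2 ratio of -4.19 (interval -4.86 to -3.68). The remaining 5 lay on chromosome 26 (4726051 to 4726985), chromosome 5 (56958985 to 56961358), chromosome 8 (22708878 to 22709899), chromosome 27 (3598288 to 3599805) and chromosome 19 (1847489 to 1848179). They held 1 to 4 ChIP and 0 to 8 input reads at st11-14, and their log2 ratios ran from -4.54 to -4.15, with exact intervals that together spanned -10.82 to -2.59. All 10 had been called only at st20, and with a pseudocount of 5 their log2 ratios ran from -4.20 to -2.64. The st11-14 input stood at 0 to 0.95 of the chromosome background over the 10 regions, and at 0.22 to 0.26 in the named chromosome 5 neighbours and the chromosome 2 region. Whether low st11-14 coverage adds to these ratios was not tested.

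Of the 534 regions higher at st20, 260 (48.7%) had a neighbour of the same class within 50 kb, against a mean of 24.7% and a highest value of 31.8% over 100 shuffles. The run with the most regions held 17 such regions among 19 union regions over 178 kb of chromosome 5 (23824477 to 24002304), with 646 st11-14 and 11716 st20 ChIP reads in the 17 regions and 547 and 5339 input reads. A run of 15 lay on chromosome 26 (4583274 to 4726985), with 501 and 8109 ChIP reads, and a run of 6 lay within 15.9 kb of chromosome 2 (68192299 to 68208207), with 68 and 2324. With the st11-14 input in place of the st20 input, 684 regions were higher at st20, and 527 of them were among the 534. As for the runs at st11-14, the shuffles were not matched on width or reads. Regions higher at st20 had a median width of 2037 bp, against 1588 bp for those called only at st20.

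**Figure D4:**
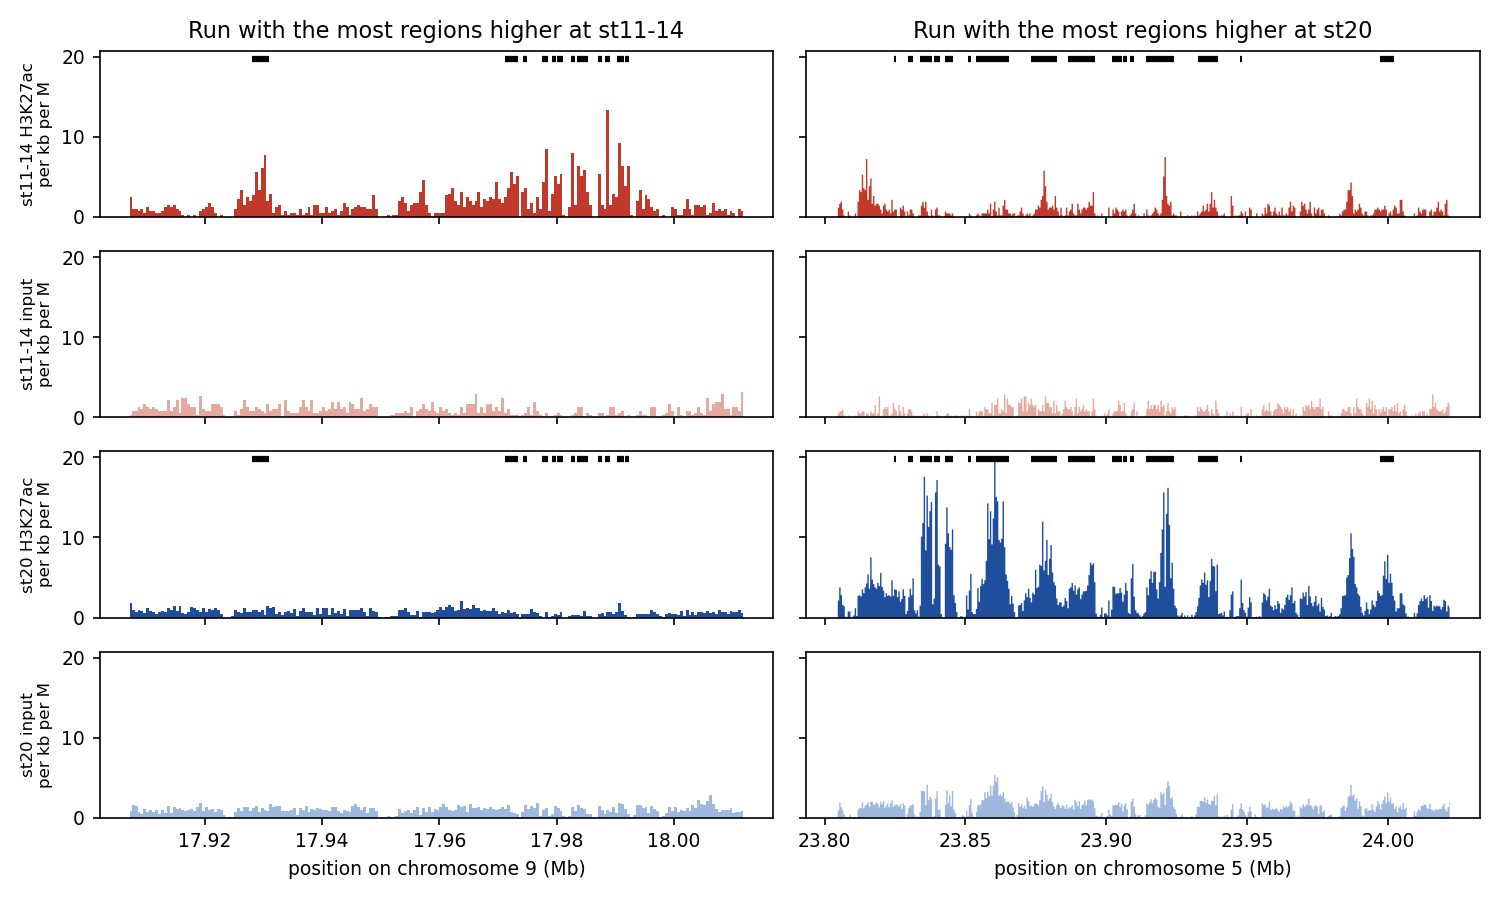
Distinct read starts per kb and per 1000000 (vertical axes, 1 scale for all panels) in 500 bp bins across the run with the most regions higher at st11-14, on chromosome 9 (left), and at st20, on chromosome 5 (right), with 20 kb on each side, 1 row per library. Black bars mark the 12 and 17 regions that passed the rule, and the ChIP of the other stage stays lower under them.

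The stages also differed in where on the karyotype the differing regions lay. Regions higher at st11-14 made up 7.62% of union regions on chromosomes 1 to 5 (95% Wilson interval 7.21 to 8.05%) and 3.02% on the small chromosomes 11 to 28 (2.67 to 3.42%). Regions higher at st20 made up 1.40% (1.22 to 1.60%) and 2.38% (2.07 to 2.74%). Of the 1190 union regions of chromosome Z, 109 (9.16%, 7.65 to 10.9%) were higher at st11-14 and 35 (2.94%, 2.12 to 4.06%) higher at st20. The inputs differed in the same direction: read starts per bp on chromosomes 11 to 28 relative to chromosomes 1 to 5 were 0.90 in the st11-14 input and 1.07 in the st20 input. In the ChIP libraries these values were 1.34 and 1.32. ChIP molecules among the st20 input reads, a candidate explanation given below, would raise the 1.07, which was not tested. Chromosomes 11 to 28 held 32.9% of regions called at both stages, 23.9% of those called only at st11-14 and 29.6% of those called only at st20. As few regions called at both stages passed the rule, this mix may add to the differences, which was not tested.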

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

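These regions were picked out because ChIP stood above input at 1 stage and below it at the other, in a single library of each kind. No difference between stages was tested, since there is 1 library per group. Of the 28 named regions, 15 had this property, all of them among the regions with the highest or lowest ratio between stages. That is in part fixed by the choice of regions. Those with extreme ratios had to pass a minimum of ChIP over input at 1 stage and have few ChIP reads at the other. The rest were chosen for many ChIP reads above input.

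The 10 regions with the highest ratio towards st11-14 all had ChIP below input at st20. They were picked for a high ratio, and hold 3 to 20 ChIP reads at st20 and 1 to 11 input reads at st11-14. In all 1747 regions higher at st11-14 the median of ChIP over input at st20 was 0.81. These values use the st20 input, which may hold ChIP molecules. Relative to chromosome background, the st20 ChIP stood at 0.33 and the st11-14 input at 0.32 at chromosome 1, 105528766 to 105530470. At the others the st20 ChIP was the lower, from 0.18 against 0.18 at chromosome 9, 17991671 to 17992419, to 0.41 against 1.33 at chromosome Z. At these 10 regions ChIP over input at st20 and st11-14 was 0.41 and 20.1 at chromosome 9, 17991671 to 17992419, and 0.34 and 12.6 at 17982395 to 17983118 of the same chromosome. It was 0.34 and 14.3 at chromosome 4, 10592304 to 10593652, and 0.39 and 11.9 at 9137161 to 9139250. On chromosome 1 it was 0.57 and 9.45 at 18061708 to 18063319, and 0.49 and 13.8 at 105528766 to 105530470. It was 0.35 and 10.2 at chromosome 7, 30108984 to 30110194, 0.45 and 5.96 at chromosome Z, 42528679 to 42529467, 0.58 and 7.55 at chromosome 5, 34618629 to 34620141, and 0.34 and 8.05 at chromosome 2, 95363606 to 95364852.

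Of the 10 regions with the lowest ratio, 5 had ChIP below input at st11-14. ChIP over input at st11-14 and st20 was 0.51 and 3.35 at chromosome 6, 16153609 to 16154759, and 0.51 and 3.38 at chromosome 5, 56958985 to 56961358. It was 0.63 and 2.41 at chromosome 26, 4726051 to 4726985, 0.35 and 2.77 at chromosome 27, 3598288 to 3599805, and 0.47 and 2.66 at chromosome 19, 1847489 to 1848179. The st11-14 values of these 5 regions rest on 1 to 4 ChIP reads and 2 to 8 input reads.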

How the results depend on the processing

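The alternatives for the control, for shared input starts, for the fragment length, for regions with high input and without a minimum of ChIP over input were chosen after the data were seen. ChIP over input in called regions was 5.84-fold at st11-14 with all deposited reads, 5.23 without the shift, 6.24 in the top scoring 50% of the list, and 3.69 with the st20 input. At st20 it was 2.83 with all reads, 2.82 in the top scoring 50%, 3.07 without input starts shared with the ChIP library and 5.13 with the st11-14 input. The share of st11-14 regions overlapping st20 was 26.1% with reciprocal overlap of 0.5, 60.0% with 6330 regions from each list, 38.9% in the top scoring 50% of each and 32.0% for 1 kb windows. In that order the share of st20 regions was 56.2%, 60.2%, 80.8% and 68.2%. Regions higher at st11-14 numbered 3281 when scaled to total reads, 7856 with input subtracted, 738 with a pseudocount of 5 and 9228 with a minimum of 2-fold. Regions higher at st20 numbered 339, 1315, 370 and 2102 in that order, and 816 with all deposited reads. With shifts set from the estimated fragment length, 142 bp at st11-14 and 58 bp at st20, 1815 regions were higher at st11-14 and 553 at st20. Of the 12 alternatives for this comparison, 4 change only the rule and leave the ratios as they are. Under the 8 others, 21 of 160 values of the 20 regions with the highest or lowest ratio left their main interval, all 10 of the highest among them with a pseudocount of 5, where they ran from 2.46 to 3.32. That interval is of counts without a pseudocount, so a higher pseudocount can pull a ratio out of it by construction. The causes of these moves were not tested, except that a lower minimum fold and a higher pseudocount widen or narrow the count by construction.

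Depth limits regions of few reads, and the st11-14 ChIP was the shallower. With the st20 ChIP thinned to its depth, 2260 and 569 regions passed, of which 1410 and 451 were the same as at full depth. No paired analysis was possible because each group has 1 library. The alternatives for promoter shares, gene lists and motifs were not run, since no gene or motif was assigned.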

Other observations

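Of the tests below, those on read starts shared between libraries, on depth at st20, on weak signal at st20 (in the form reported), on signal in the st20 control and on neighbouring pairs 50 to 500 kb apart were chosen only after the result was seen, and the domains and single regions named here were chosen after their values were seen.

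When called regions were stitched, the st11-14 regions formed 13116 domains, of which 7381 were a single region, and the st20 regions formed 7264, of which 4554 were a single region. The widest domain of each stage was the same stretch of chromosome 5. At st11-14 it ran from 30632275 to 30887668 with 48 regions, and at st20 from 30615952 to 30822337 with 27 regions. The next widest at st11-14 lay on chromosome 14 (4124479 to 4270486), with 27 regions and 13 st20 regions inside. At st20 they lay on chromosome 26 (4583274 to 4726985), with 22 regions, and on chromosome 5 (23804677 to 23948115), with 19. These contained 6 and 4 st11-14 regions. On chromosome 21, a st20 domain from 2870895 to 3003289 had 3.35 st20 ChIP starts per kb and per 1000000 starts, and 1.40 in the st11-14 ChIP.

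The st20 ChIP and st20 input shared 2049621 exact read starts, 3.56 times as many as at positions 1 bp apart. The highest such ratio among the other 5 pairs of libraries was 1.046, which argues against positions that map more often in every library. Of the excess of shared starts, 13.97% lay in st20 regions, close to the 13.9% of the st20 ChIP, and the share stood 8.68 percentage points above that of the st20 input, which argues against input DNA in the ChIP reads. A candidate explanation is that molecules of the ChIP library are among the input reads. The excess of shared starts was 4.62% of the distinct starts of the st20 input. If the st20 input otherwise followed the st11-14 input, 23.1% of its reads would come from the ChIP library. The 23.1% rests on that assumption, and why it is larger than the 4.62% was not tested. Whether the shared starts arose in the laboratory, in sequencing or in file handling stays open, and no biological explanation was tested.

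Fewer regions were called at st20 than at st11-14. Lower depth is argued against, since the st20 ChIP library was 2.99 times as deep. In the regions called only at st11-14, the rise of the st20 ChIP from flank to centre was 1.38 times that of the st11-14 input (1.54 times for medians over background, a form of the test run first and replaced) but 1.21 times that of the st20 input, in line with weak signal below the calling threshold in part of them. The st20 regions held 1.95 times as large a share of st20 input as of st11-14 input reads, so signal in the control may also have lowered the number called. A smaller number of acetylated regions in frontonasal cells, and the difference between cultured and dissected cells, stay open.

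Neighbouring regions tended to differ between stages in the same direction. Of 24232 neighbouring pairs within 50 kb, 71.8% had log2 ratios of the same sign, against at most 62.1% in 100 shuffles within blocks of 2 Mb, which argues against a trend over whole chromosomes, and pairs 50 to 500 kb apart, with 70.5% against at most 66.9%, show that the pattern was not confined to close neighbours. Among 9749 pairs 10 to 50 kb apart the share was 66.5% against at most 63.1%, so the pattern was not confined to calls less than 10 kb apart. Stitched domains reached 255 kb, so this test cannot decide whether calls split from 1 domain are the cause. Among 9964 pairs of regions whose inputs differed by less than 1.5-fold between stages it was 79.1% against at most 74.6%, which argues against a copy number or mapping difference as the whole cause. Shared regulation of neighbouring regions between the stages may contribute, as a hypothesis found and tested on the same libraries, and a bias below that size shared by neighbours stays open. The sign also largely follows the list in which a region was called. It was positive in 97.3% of regions called only at st11-14 and in 0.032% of those called only at st20. These shuffles, unlike those for runs, were not matched on the calling stage, so they cannot separate the pattern from clustering of calls of 1 list.

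Across union regions, which are not independent replicates, the log2 ratio between stages and the log2 ratio of the inputs had a Spearman rho of 0.55, and ChIP density had a rho of 0.08 between stages. In the regions called at both stages the rho of ChIP density was 0.34. The union includes 17122 regions called only at st11-14 and 3125 called only at st20, and this selection can lower the rho of 0.08. ChIP molecules among the st20 input reads, the candidate explanation above, would raise the rho of 0.55, which was not tested.

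The 10 highest scores of the st11-14 list all belonged to regions where the st11-14 input stood at 4.45 to 13.6 times the chromosome background. The st20 region on chromosome 1 at 199355223 to 199355843, ranked 3 in its list with a deposited score of 100.4, held 175 ChIP and 132 input reads at st20 but 3 and 1 at st11-14. A region of chromosome 2 at 75149078 to 75149616 held 66 and 50 at st20 but 1 and 0 at st11-14.

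Read starts per bp on chromosome Z relative to chromosomes 1 to 5 were 0.76 in the st11-14 input and 0.74 in the st20 input.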
